A study of Mus musculus with 2197 samples.

How the data were processed

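Single mouse embryonic pancreatic cells were profiled by Smart-seq2, and whole digested E14.5 pancreas by 2 droplet libraries (10x Genomics). Per the labels' protocols, cells were sorted on fluorescent reporters, Smart-seq2 cDNA was amplified by PCR without molecular identifiers, and explants were dorsal pancreata of E13.0 cultured with or without U0126. Per the submitters' processing notes, the authors made the deposited Smart-seq2 read counts on mm10 with TopHat2 2.1.0, Bowtie2 and HTSeq 0.6.0 and the deposited droplet UMI counts with Cell Ranger 2.0.2. The role of each tool and the gene annotation are not given. The deposited table of Smart-seq2 read counts held whole numbers for 40824 genes and 92 ERCC spike-ins, 1 column per cell, with no normalization and no pooling of cells. The deposited TPM values of the authors were not used. Each column matched 1 sample title, no cell's counts were identical to another's, and ERCC counts were left out of all totals. No mitochondrially encoded gene had a count in the Smart-seq2 table, so that list could not be tested.

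The unit of replication was the set, the number that precedes the cell number in a title, since cells are not replicates. The labels do not say what a set is. Counts were summed over the cells of a set (6 to 71 cells, at least 2838610 counts). Groups, comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Genes were tested with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood F test) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Groups of few sets shared 1 fit and 1 estimate of the spread, namely the Ngn3-GFPhigh and Ngn3-GFPlow groups of all days, the E15.5 groups, the Pdx1-GFP groups, the Ngn3-GFP+ and Sox9-CreER groups, and the E11.5 lineage groups. Standard errors are the log2 fold change over the root of F, and p-values measure only the spread between sets, which may be technical. The Gcg-GFP+ E17.5 cells came from 1 set and entered no test.

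Named genes were the 8 with the largest positive and the 8 with the largest negative log2 fold change among those that passed, with a mean of at least 50 CPM in 1 group and every set of one group above every set of the other, plus members of the lists. Such separation arises by chance in 10% of genes for 3 sets against 3 and in 33.3% for 2 against 2. It was seen in 26.2% of genes at E13.5 and 54.1% at E15.5 between the Ngn3-GFP sorts, and in 43.6% between Ins1-RFP+ and Gcg-GFP+ cells. The 24 lists (16 of cell types and 8 of processes) were tested with limma 3.58.1 camera (two-sided, preset correlation 0.01, adjusted over the lists of a comparison), with camera at an estimated correlation and fry beside it. Over all comparisons 122 list tests passed with the preset correlation and 10 with an estimated one. List calls that the text leaves out did not pass with an estimated correlation. The 10 were the beta cell list in 6 comparisons and the acinar, alpha cell, late endocrine precursor and leukocyte lists in 1 each. Fry's p tests whether a list's genes move one way on balance and compares them with no other genes. The gut and stomach list and the neural and glial list passed in no comparison. The cholesterol synthesis list, with 1 of 14 members higher in Ngn3-GFPhigh cells at E13.5 (3 adjusted over the list alone), had adjusted p = 0.000328 by camera and 0.427 with an estimated correlation. A fold against a group without any count was computed against a floor of 3 counts over the group and is written as a lower bound. Floors and intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Gene positions are those of the mm10 assembly (GRCm38) in the GENCODE annotation, matched by gene identifier.

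Smart-seq2 cells were clustered with scanpy 1.11.5 (2000 variable genes, 30 components, 15 neighbours, resolution 1.0, 20 clusters), and a cluster was named by at least 3 markers of a list. Alpha-like cells were those of 3 clusters, and sets with at least 5 of them were used. Shares of cells over 100 CPM were compared per set with exact permutation tests, or with 100000 permutations for the correlation with day, both two-sided (scipy 1.17.1). Droplet barcodes with at least 1000 genes and at most 10% mitochondrial counts were kept, doublets were removed (4 of 3406 and 189 of 6764), and each library was clustered alone (19 and 21 clusters). Droplet clusters were named by a marker score of at least 0.4. Of 3 ways of naming tried, this one was chosen after their output was seen, so the class shares are descriptive. Intervals of shares are exact (Clopper-Pearson).

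Tests were checked on simulated counts with 200 changed genes in each fit. At changes of 1, 2 and 3 log2 units, calls were made for 1.52%, 21.2% and 44.1% of changed genes between the Ngn3-GFP sorts at E13.5. The shares were 7.35%, 40.6% and 54.4% in the trend and 0%, 10.1% and 24.3% between Ins1-RFP+ and Gcg-GFP+ cells. In the trend a change was the whole change from E10.5 to E15.5 and not a slope per day. Whether shared set numbers pair the sets was judged by the correlation of same-numbered sets' deviations from their group means. Among comparisons with at least 3 pairs, it was over 0.1 for every pair only for U0126 and control (0.168, 0.151, 0.149 and 0.299) and for the Ngn3-GFP sorts at E13.5 (0.229, 0.110 and 0.104), where the block value is given beside the result. With 2 pairs, too few to decide, it was 0.135 and 0.135 for Ngn3-Cre and Pdx1-Cre at E11.5. Alternatives set down then were RLE size factors, a DESeq2 1.42.0 Wald test, limma on log2 mean CPM per cell plus 1, and no filter on low counts. So were only sets of at least 10 cells, the set number as a block, other thresholds, other cluster resolutions and leaving out each set. A quality filter on cells (under 2000 genes or under 0.1 of the median total) removed 0 cells and was not run further. Chosen after the data were seen were the fits without the 219 cells with at least 4 markers of other types at 100 CPM and without the sets with a tissue tag in their titles. So were those at E16.5 or E17.5 alone and without parts of the alpha-like cells, a marker score of 0.3 and a joint clustering of the droplet libraries. For the ERK list under U0126, no filter and only sets of at least 10 cells were also chosen then. Steps before the counts were not repeated.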

Results

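The data were single-cell transcriptomes of sorted mouse embryonic pancreatic cells from E9.5 to E17.5 (E, embryonic day), made with Smart-seq2, a plate-based full-length protocol. To these came 2 droplet libraries (10x Genomics) of whole E14.5 pancreas. The Smart-seq2 part held 2195 cells of 29 groups in 82 sets, a set being the number shared by cells of one group in the sample titles. Some cells were sorted on the Pdx1 reporter, as Pdx1-GFP+ (113 cells in 3 sets at E9.5, 42 in 2 at E10.5 and 60 in 2 at E11.5) or Pdx1-GFPhigh (27 in 2 at E10.5). Cells with the Neurog3 reporter were Ngn3-GFP+ (62 in 3 at E10.5, 121 in 3 at E12.5, 130 in 4 at E16.5 and 125 in 4 at E17.5). At E13.5, E14.5 and E15.5 they were sorted into Ngn3-GFPhigh (77 in 3, 108 in 3 and 51 in 2) and Ngn3-GFPlow (118 in 3, 104 in 5 and 37 in 2). Hormone reporters gave Ins1-RFP+ (39 in 2 at E15.5) and Gcg-GFP+ cells (36 in 2 at E15.5 and 11 in 1 at E17.5). Cells marked by a Cre driver and a Rosa-RFP reporter were Pdx1-Cre at 6 days. They numbered 80 in 2 sets at E10.5, 80 in 2 at E11.5, 131 in 4 at E12.5 and 108 in 4 at E13.5. At E14.5 there were sets of 6, 15, 61 and 44 cells, and at E15.5 79 cells in 3 sets. Other drivers were Ptf1a-CreER (79 in 3) and Ngn3-Cre (44 in 2) at E11.5, and Sox9-CreER (55 in 2 at E16.5 and 34 in 2 at E17.5). Ins1-RFP+ cells were also sorted from E13.0 dorsal pancreata kept in culture with the MEK inhibitor U0126 (60 in 4) or without it (58 in 4). A Smart-seq2 cell had 176524 to 2118160 gene counts (median 809389) and 4339 to 12149 detected genes (median 7981). Values below are means ± SD over sets in CPM, counts scaled to a common library total. Log2 fold changes are given ± their standard error, and adjusted p-values come from edgeR's quasi-likelihood test unless another test is named.

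Cells with a strong or a weak signal of the Neurog3 reporter were compared on each of 3 days. The sort in part sets the level of Neurog3. Ngn3-GFPlow cells were of several types, so the contrast is not one of stages alone. Of 118 such cells at E13.5, 27 fell in 1 cluster with alpha cell markers and 52 in the one with leukocyte markers. The same clusters held 0 and 15 of 37 cells at E15.5. At E13.5, Neurog3 itself (ENSMUSG00000044312, mm10 chromosome 10, 62133090 to 62134763), the transcription factor that commits pancreatic cells to the endocrine fate, was higher in Ngn3-GFPhigh than in Ngn3-GFPlow cells (1007 ± 97.0 against 118 ± 147 CPM, n = 3 sets each). Pax4, which directs cells toward the beta and delta fates, stood at 579 ± 100.5 against 27.7 ± 37.2 CPM, a log2 fold change of 4.38 ± 1.12 (adjusted p = 0.0313, edgeR). The growth arrest gene Gadd45a (log2 fold change 3.88), the transcription factor Lhx1 (5.22), the Notch ligand-related Dner (6.36) and Tgm7 (7.62) were higher, and Neurod2 was at least 467-fold higher. Of 14 tested endocrine progenitor genes, 9 passed as higher (10 adjusted over the list alone), at adjusted p = 7.94e-12 by camera and 0.109 with an estimated correlation. Genes of the cell cycle were lower in Ngn3-GFPhigh cells. Of 18 tested G2/M genes, 9 passed as lower (18 adjusted over the list alone), at adjusted p = 1.07e-12 by camera and 0.237 with an estimated correlation. Of 16 tested S phase genes, 7 passed as lower (14 adjusted over the list alone), at adjusted p = 9.77e-10 by camera and 0.237 with an estimated correlation. Top2a, a topoisomerase of dividing cells, had a log2 fold change of -4.89, the growth regulator Myc -6.99 and the Notch target Hes1 -5.64. Markers of leukocytes were lower as well. Of 8 tested leukocyte genes, 7 passed as lower (8 adjusted over the list alone), at adjusted p = 1.44e-06 by camera and 0.337 with an estimated correlation. Csf1r, the receptor of the macrophage growth factor, stood at 1.05 ± 0.591 against 1485 ± 1178 CPM, and the complement gene C1qb and the phosphatase gene Inpp5d had log2 fold changes of -10.84 and -11.52. Gpr65 was at least 1640-fold and Cd200r1 at least 1410-fold lower. Of the Ngn3-GFPlow cells, 51 of 118 (43.2%) carried at least 4 leukocyte markers at 100 CPM or more, against 0 of 77 Ngn3-GFPhigh cells, which allows a share of up to 3.90%. The 51 cells held 99.7% of the sort's leukocyte-list counts. Of 8 tested endothelium genes, 1 passed as lower (5 adjusted over the list alone), at adjusted p = 0.0141 by camera and 0.427 with an estimated correlation. Of 8 tested liver genes, 0 passed as lower (0 adjusted over the list alone), at adjusted p = 0.0290 by camera and 0.477 with an estimated correlation. Liver markers were carried by 4 of the 118 cells (3.39%) and endothelium markers by 1. Ins2 did not pass the test at this day (log2 fold change 0.44 ± 1.52, adjusted p = 0.923, edgeR).

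In all, 1181 of 18989 tested genes passed at E13.5, 305 higher and 876 lower in Ngn3-GFPhigh cells. The median log2 fold change of all tested genes was -0.14. With the set number as a replicate block 732 passed, 226 higher and 506 lower, and Lhx1 and Hes1 lost their calls. Without the cells that carried markers of other cell types, an alternative chosen after the data were seen, 156 genes passed, 65 higher and 91 lower, and Neurog3, Gadd45a, Tgm7, Dner, Top2a, Myc, Csf1r, C1qb, Inpp5d, Gpr65 and Cd200r1 no longer did. The count was 408, 511 or 608 without Ngn3-GFPhigh set 1, 2 or 3 and 523 without Ngn3-GFPlow set 2, and Pax4, Neurog3, Gadd45a, Lhx1 and Tgm7 each lost their call in 5 of 6 such fits. Cd200r1 lost its call in 4, C1qb, Csf1r and Hes1 in 3, and Gpr65 and Top2a in 2. Without Ngn3-GFPlow set 1 the log2 fold change of Hes1 was -3.69.

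At E14.5, the hormone gene Ins2 (ENSMUSG00000000215, mm10 chromosome 7, 142678656 to 142743381) separated the sorts, with 4748 ± 3309 against 1.80 ± 1.86 CPM (n = 3 and 5 sets, log2 fold change 11.37 ± 1.85, adjusted p = 0.00138, edgeR). Npy, which encodes neuropeptide Y, had a log2 fold change of 11.81, and the islet phosphatase gene G6pc2 one of 9.997. Fev, a transcription factor of late endocrine precursors, stood at 257 ± 10.3 against 1.99 ± 3.09 CPM, and the transcription factor Neurod1 (5.40) and the granule protein gene Chgb (6.92) were higher in Ngn3-GFPhigh cells too. Of 18 tested beta cell genes, 14 passed as higher (16 adjusted over the list alone), at adjusted p = 1.29e-11 by camera and 0.0388 with an estimated correlation. Of 10 tested late endocrine precursor genes, 9 passed as higher (10 adjusted over the list alone), at adjusted p = 1.93e-07 by camera and 0.0516 with an estimated correlation. Of 14 tested endocrine progenitor genes, 4 passed as higher (8 adjusted over the list alone), at adjusted p = 0.000901 by camera and 0.323 with an estimated correlation. Of 17 tested pan-endocrine genes, 7 passed as higher (10 adjusted over the list alone), at adjusted p = 4.29e-09 by camera and 0.225 with an estimated correlation. Of 12 tested alpha cell genes, 5 passed as higher (9 adjusted over the list alone), at adjusted p = 7.39e-06 by camera and 0.323 with an estimated correlation. Spp1 (ENSMUSG00000029304, mm10 chromosome 5, 104435118 to 104441050), a secreted glycoprotein of duct cells, was lower at 192 ± 80.05 against 8849 ± 6535 CPM. Other duct genes were lower as well, with log2 fold changes of -5.87 for Hes1 and -3.40 for Sox9, while Vtcn1 was at least 125-fold lower. Of 14 tested duct genes, 8 passed as lower (11 adjusted over the list alone), at adjusted p = 3.21e-05 by camera and 0.281 with an estimated correlation. Of 16 tested S phase genes, 15 passed as lower (16 adjusted over the list alone), at adjusted p = 3.39e-17 by camera and 0.0516 with an estimated correlation. The replication licensing gene Cdc6 had a log2 fold change of -7.33. Of 18 tested G2/M genes, 12 passed as lower (18 adjusted over the list alone), at adjusted p = 9.06e-13 by camera and 0.225 with an estimated correlation. Of 12 tested Notch pathway genes, 3 passed as lower (4 adjusted over the list alone), at adjusted p = 0.0399 by camera and 0.356 with an estimated correlation. Of 8 tested leukocyte genes, 7 passed as lower (8 adjusted over the list alone), at adjusted p = 7.39e-06 by camera and 0.310 with an estimated correlation. C1qb had a log2 fold change of -14.77 and Ms4a4a was at least 5180-fold lower. Cells with leukocyte markers made up 31 of 104 Ngn3-GFPlow cells (29.8%) and 0 of 108 Ngn3-GFPhigh cells, which allows up to 2.78%. In all, 2857 of 18989 genes passed, 1147 higher and 1710 lower. With the set number as a replicate block 1173 passed. Same-numbered sets correlated at 0.214, 0.0746 and 0.102, so that 1 pair fell under the 0.1 asked of every pair. Without the cells with markers of other types 1774 passed, 949 higher and 825 lower, and C1qb lost its call. With log2 mean CPM per cell in limma, the split was 2152 higher and 1560 lower. The count was 1787, 1700 or 1571 without Ngn3-GFPhigh set 1, 2 or 3. Vtcn1 lost its call in 7 of 8 fits without 1 set and Sox9 in 4.

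At E15.5 (n = 2 sets each), the incretin receptor gene Gipr was at least 906-fold higher in Ngn3-GFPhigh cells and the phosphatase regulator Ppp1r1a at least 1360-fold. The microtubule gene Mapt was at least 1090-fold higher, Peg10 at least 1850-fold, Lhx1 at least 795-fold and the transcription factor Mnx1 at least 237-fold. Pdx1, which is kept in beta cells, stood at 444 ± 16.2 against 54.5 ± 0.261 CPM (log2 fold change 3.03 ± 0.57, adjusted p = 0.00679, edgeR), and Npy had a log2 fold change of 12.54. Spp1 was lower, with 48.5 ± 45.3 against 5381 ± 755 CPM, and Cdc6 and Ncapg, both active in cycling cells, were at least 612-fold and 1660-fold lower. The leukocyte genes Ly86 and Itgb2 were at least 3460-fold and 1920-fold lower. Leukocyte markers were carried by 13 of 37 Ngn3-GFPlow cells (35.1%) and 0 of 51 Ngn3-GFPhigh cells, which allows up to 5.88%. Of 18 tested beta cell genes, 13 passed as higher (15 adjusted over the list alone), at adjusted p = 3.75e-13 by camera and 0.0239 with an estimated correlation. Of 10 tested late endocrine precursor genes, 5 passed as higher (7 adjusted over the list alone), at adjusted p = 1.6e-08 by camera and 0.0458 with an estimated correlation. Of 17 tested pan-endocrine genes, 6 passed as higher (17 adjusted over the list alone), at adjusted p = 1.95e-11 by camera and 0.167 with an estimated correlation. Of 16 tested S phase genes, 14 passed as lower (16 adjusted over the list alone), at adjusted p = 1.34e-16 by camera and 0.0575 with an estimated correlation. Of 18 tested G2/M genes, 13 passed as lower (17 adjusted over the list alone), at adjusted p = 3.75e-13 by camera and 0.189 with an estimated correlation. Of 14 tested duct genes, 4 passed as lower (10 adjusted over the list alone), at adjusted p = 0.000232 by camera and 0.290 with an estimated correlation. Of 8 tested leukocyte genes, 7 passed as lower (7 adjusted over the list alone), at adjusted p = 0.000251 by camera and 0.363 with an estimated correlation. In all, 1706 genes passed, 646 higher and 1060 lower. Without the cells with markers of other types 785 passed, 368 higher and 417 lower, and Mnx1, Peg10, Ly86 and Itgb2 lost their calls. The count was 431 or 354 without Ngn3-GFPhigh set 1 or 2 and 742 or 404 without Ngn3-GFPlow set 1 or 2. Peg10, Itgb2 and Mnx1 lost their calls in each of these 4 fits, Ly86 in 3 and Pdx1 in 1. The other genes with a lower bound, except Cdc6, lost theirs in 2, as did Npy and Spp1.

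**Figure D1:**
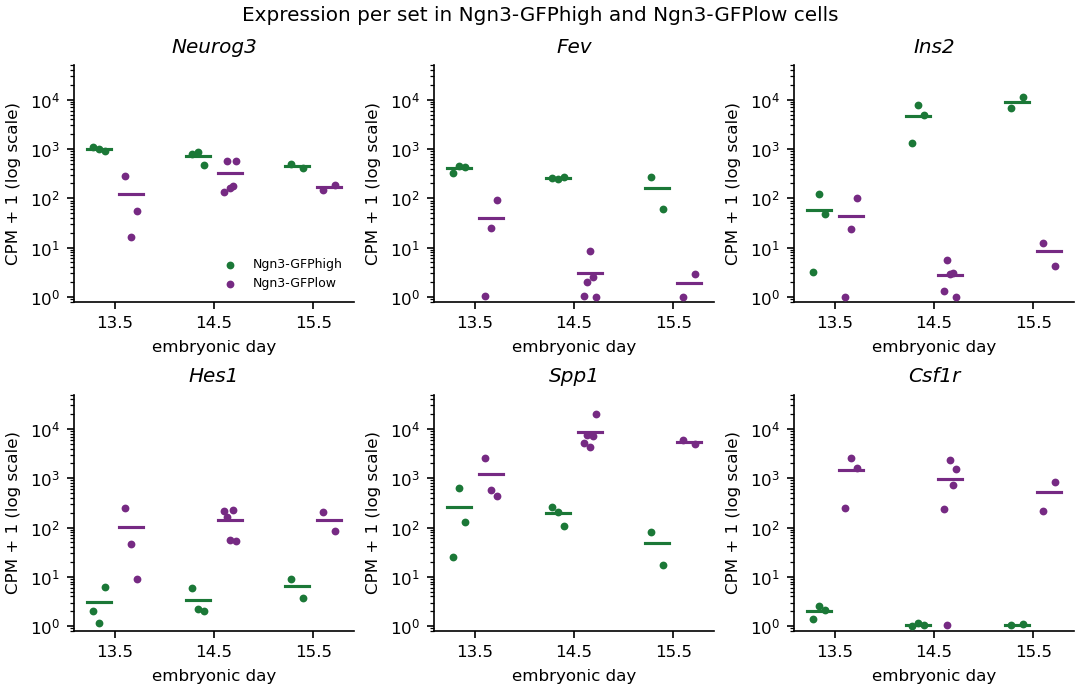
Mean CPM plus 1 on a log axis of 6 genes in Ngn3-GFPhigh (green) and Ngn3-GFPlow (purple) cells at E13.5, E14.5 and E15.5; points are sets and bars the mean of the sets. Ins2 averaged 4748 CPM in Ngn3-GFPhigh and 1.80 CPM in Ngn3-GFPlow cells at E14.5, while Csf1r averaged 1.05 and 1485 CPM at E13.5.

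Whether the difference between the sorts itself changed from E13.5 to E15.5 was tested as an interaction. The mix of Ngn3-GFPlow cells changed too, with 27 of 118 in a cluster with alpha cell markers at E13.5 and 0 of 37 at E15.5. The test cannot tell such a change of mix from a change within a cell type. The log2 difference of the interaction was 22.09 for Npy (adjusted p = 0.0106, edgeR), which was lower in Ngn3-GFPhigh cells at E13.5 and higher at E15.5. The size of this difference rests on near-absent counts, since Npy stood at 0.0228 ± 0.0396 against 13.4 ± 14.2 CPM at E13.5. The precursor gene Vwa5b2 had a log2 difference of 7.98 (adjusted p = 0.00939, edgeR) and the potassium channel subunit gene Abcc8, which links glucose to insulin release, one of 4.06 (adjusted p = 0.0205, edgeR). Of 18 tested beta cell genes, 1 passed as more positive (14 adjusted over the list alone), at adjusted p = 3.1e-12 by camera and 0.0274 with an estimated correlation. In all, 23 genes passed, 14 with a more positive and 9 with a more negative difference at E15.5. Without the cells with markers of other types 39 passed, 28 more positive and 11 more negative. With the set number as a block 2 passed, and Vwa5b2 and Abcc8 lost their calls. Of the 10 fits without 1 set, Abcc8 lost its call in 7, Npy in 2 and Vwa5b2 in 1. Without 1 set the count was 14 (Ngn3-GFPhigh E13.5 set 1 or Ngn3-GFPlow E15.5 set 1), 10 (Ngn3-GFPhigh E15.5 set 2 or Ngn3-GFPlow E13.5 set 2 or 3), 7 (Ngn3-GFPlow E15.5 set 2) or 238 (Ngn3-GFPlow E13.5 set 1).

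Ngn3-GFP+ cells of E10.5 and E12.5 were compared with those of E16.5 and E17.5 to set first-wave against later endocrine cells of one reporter (n = 6 and 8 sets). The insulin genes were lower in the early cells. Ins1 stood at 179.1 ± 71.7 against 17400 ± 18370 CPM (log2 fold change -6.59 ± 0.92) and Ins2 at 14.9 ± 10.9 against 33130 ± 32240 CPM (-11.16 ± 1.19, adjusted p = 4.43e-05, edgeR). Reads of these near-identical copies could be split or shared by the authors' counting, so their separate levels are uncertain. The granule docking gene Sytl4 (-8.07), the GABA-synthesis gene Gad1 (-8.48), Mapt (-5.91), the somatostatin gene Sst (-9.15) and Neurog3 (-4.34) were lower as well. The glucagon gene Gcg (ENSMUSG00000000394, mm10 chromosome 2, 62474530 to 62483650) did not pass the test and stood at 24580 ± 8288 against 17490 ± 8241 CPM (log2 fold change 0.50 ± 0.56, adjusted p = 0.594, edgeR). Higher in the early cells were the serotonin-synthesis gene Tph1 (5.47), the foregut transcription factor Gata4 (2.82), the apolipoprotein gene Apoa1 (6.66) and the fatty acid binding protein gene Fabp7, the last at least 554-fold. Of 17 tested beta cell genes, 16 passed as lower (17 adjusted over the list alone), at adjusted p = 2.13e-19 by camera and 0.0364 with an estimated correlation. Of 12 tested unfolded protein response genes, 8 passed as lower (11 adjusted over the list alone), at adjusted p = 9.34e-06 by camera and 0.276 with an estimated correlation. Of 17 tested pan-endocrine genes, 10 passed as lower (11 adjusted over the list alone), at adjusted p = 3.4e-06 by camera and 0.309 with an estimated correlation. Of 12 tested immediate early genes, 5 passed as lower (6 adjusted over the list alone), at adjusted p = 0.00380 by camera and 0.276 with an estimated correlation. Of 16 tested S phase genes, 14 passed as higher (16 adjusted over the list alone), at adjusted p = 7.95e-08 by camera and 0.276 with an estimated correlation. Of 9 tested liver genes, 6 passed as higher (8 adjusted over the list alone), at adjusted p = 0.000301 by camera and 0.0882 with an estimated correlation. Of 8 tested endothelium genes, 6 passed as higher (7 adjusted over the list alone), at adjusted p = 0.00428 by camera and 0.335 with an estimated correlation. Liver markers were carried by 1 of 62 cells at E10.5 and 4 of 121 at E12.5, against 0 of 130 at E16.5 and 0 of 125 at E17.5. Endothelium markers were carried by 1 of 121 at E12.5 and by no cell of the other days. Of 8 tested leukocyte genes, 8 passed as higher (8 adjusted over the list alone), at adjusted p = 7.52e-08 by camera and 0.243 with an estimated correlation. Of 8 tested erythroid genes, 1 passed as higher (1 adjusted over the list alone), at adjusted p = 0.0464 by camera and 0.407 with an estimated correlation. The fractalkine receptor gene Cx3cr1 of macrophages had a log2 fold change of 8.79. Cells with at least 4 leukocyte markers numbered 13 of 62 at E10.5 (20.97%) and 38 of 121 at E12.5 (31.4%), against 0 of 130 at E16.5 (up to 2.31%) and 1 of 125 at E17.5. In all, 3757 of 19059 genes passed, 2177 higher and 1580 lower in the early cells. Without the cells with markers of other types 2268 passed, 1099 higher and 1169 lower, so that the excess of higher genes was gone, and Cx3cr1 and Neurog3 lost their calls. Neurog3 also lost its call in 9 of 14 fits without 1 set, and Tph1 and Gata4 in 1 fit each, without E10.5 set 2 (Tph1 3.26) and E10.5 set 1. Apoa1 kept its call but had 5.46 without E10.5 set 2.

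Counted as the share of Ngn3-GFP+ cells with at least 100 CPM of a hormone gene, the early and late sets differed in 5 of 9 genes (exact permutation test, two-sided, on shares per set, Benjamini-Hochberg over the 9). The shares are of all sorted cells. Leukocyte markers were carried by 13 of 62 cells at E10.5 and 38 of 121 at E12.5, against 0 of 130 at E16.5 and 1 of 125 at E17.5. Early shares may therefore be lower than among the other early cells. Gcg was over 100 CPM in 50.4% ± 18.0 of early and 23.7% ± 5.64 of late cells (exact permutation test, adjusted p = 0.00450), and the ghrelin gene Ghrl in 29.4% ± 17.47 and 9.56% ± 8.17 (exact, adjusted p = 0.0110). Ins2 was over 100 CPM in 2.2% ± 2.69 and 55.6% ± 24.2 (exact, adjusted p = 0.00450), Ins1 in 21.6% ± 13.8 and 49.7% ± 21.6 (exact, adjusted p = 0.0378), and Sst in 1.96% ± 4.80 and 9.54% ± 4.85 (exact, adjusted p = 0.0378). Shares of 4 genes did not pass. These were Neurog3 (2.55% ± 5.00 and 10.7% ± 6.89, exact, adjusted p = 0.0505) and Ppy (8.28% ± 8.64 and 19.4% ± 8.23, exact, adjusted p = 0.0504). The others were Fev (8.34% ± 6.11 and 15.48% ± 11.4, exact, adjusted p = 0.215) and Pyy (56.3% ± 17.1 and 60.5% ± 12.2, exact, adjusted p = 0.603). At 10 CPM, 3 genes passed and Gcg and Sst did not. The count was 3 without any 1 of E10.5 set 1, E12.5 set 1 or 3, E16.5 set 1 or E17.5 set 1 or 2, and 7 without E17.5 set 4. Sst lost its call in 10 and Ins1 in 9 of these 14 tests, and Neurog3 and Ppy each gained one in 3.

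**Figure D2:**
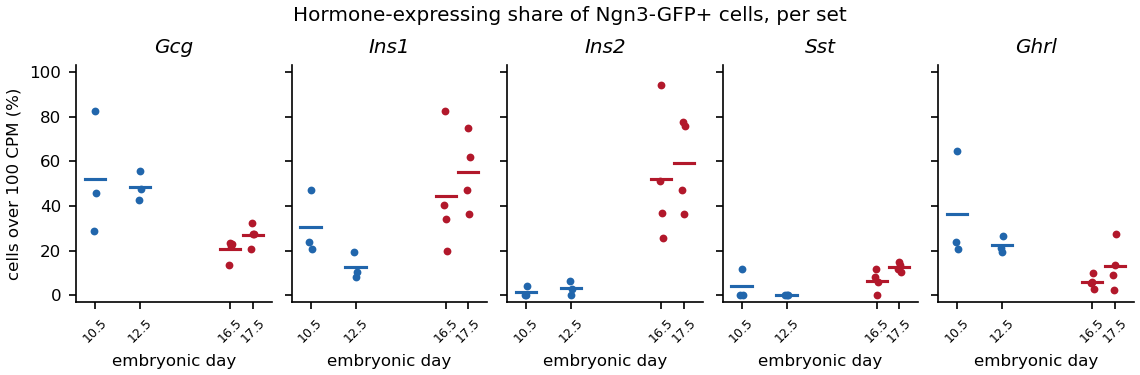
Percent of Ngn3-GFP+ cells with at least 100 CPM of Gcg, Ins1, Ins2, Sst and Ghrl at E10.5 and E12.5 (blue) and at E16.5 and E17.5 (red); points are sets and bars the mean of the sets. Over both early days the Ins2 share averaged 2.2%, and over both late days 55.6%.

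Among the Ngn3-GFP+ cells, those of clusters with alpha cell markers were compared between the early and late days, to set glucagon cells of the first wave against later ones (n = 6 and 7 sets with at least 5 such cells). Gcg did not pass the test, with 47430 ± 8312 against 53970 ± 20860 CPM (log2 fold change -0.19 ± 0.23, adjusted p = 0.727, edgeR). The plasma glycoprotein gene Vtn (ENSMUSG00000017344, mm10 chromosome 11, 78499091 to 78502324) was higher in the early cells, with 77.0 ± 26.6 against 0.129 ± 0.151 CPM (log2 fold change 9.12 ± 0.57, adjusted p = 3.88e-07, edgeR). Prtg, a membrane protein of early embryonic tissue, had a log2 fold change of 6.93 and the Notch ligand gene Dll3 one of 5.55. Also higher were the glycolytic gene Ldha (5.30), the neurofilament gene Nefl (5.12) and the mitosis gene Birc5 (5.76). The homeobox gene Meis2 was lower in the early cells, with 33.7 ± 24.98 against 576 ± 151 CPM (log2 fold change -4.09 ± 0.40). So were the amino acid transporter gene Slc7a8 (-4.11), Ripply3 (-3.91), Slitrk6 (-6.84), the immediate early gene Ier2 (-3.51) and Ins2 (-6.62). The Ins2 value rests in part on E17.5 set 2, without which it was -4.85, and Birc5 had 4.09 without E10.5 set 1. Of 17 tested pan-endocrine genes, 5 passed as lower (7 adjusted over the list alone), at adjusted p = 4.28e-05 by camera and 0.254 with an estimated correlation. Of 15 tested beta cell genes, 4 passed as lower (9 adjusted over the list alone), at adjusted p = 0.000139 by camera and 0.254 with an estimated correlation. Of 11 tested immediate early genes, 4 passed as lower (6 adjusted over the list alone), at adjusted p = 4.28e-05 by camera and 0.254 with an estimated correlation. Of 15 tested G2/M genes, 3 passed as higher (14 adjusted over the list alone), at adjusted p = 4.28e-05 by camera and 0.301 with an estimated correlation. Of 7 tested liver genes, 3 passed as higher (3 adjusted over the list alone), at adjusted p = 0.00626 by camera and 0.301 with an estimated correlation. Of the 95 early cells 78 fell in cluster 1 and 15 in cluster 2, and of the 73 late cells 72 in cluster 0. The arms were set by day with the cells of all 3 clusters pooled, so this is not a test of cluster against cluster. Since the clusters nearly coincide with the arms, the choice of cells by cluster may still shape which genes differ. At least 1000 CPM of Ins2 was found in 0 of 95 early (up to 3.16%) and 9 of 73 late cells, and the median total was 1109850 and 803876 counts. In all, 893 of 13006 genes passed, 404 higher and 489 lower in the early cells. In limma on log2 mean CPM per cell the split was 993 and 586. With only sets of at least 10 cells 420 genes passed, and Prtg, Ldha and Birc5 lost their calls, while 575 passed without E10.5 set 2.

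**Figure D3:**
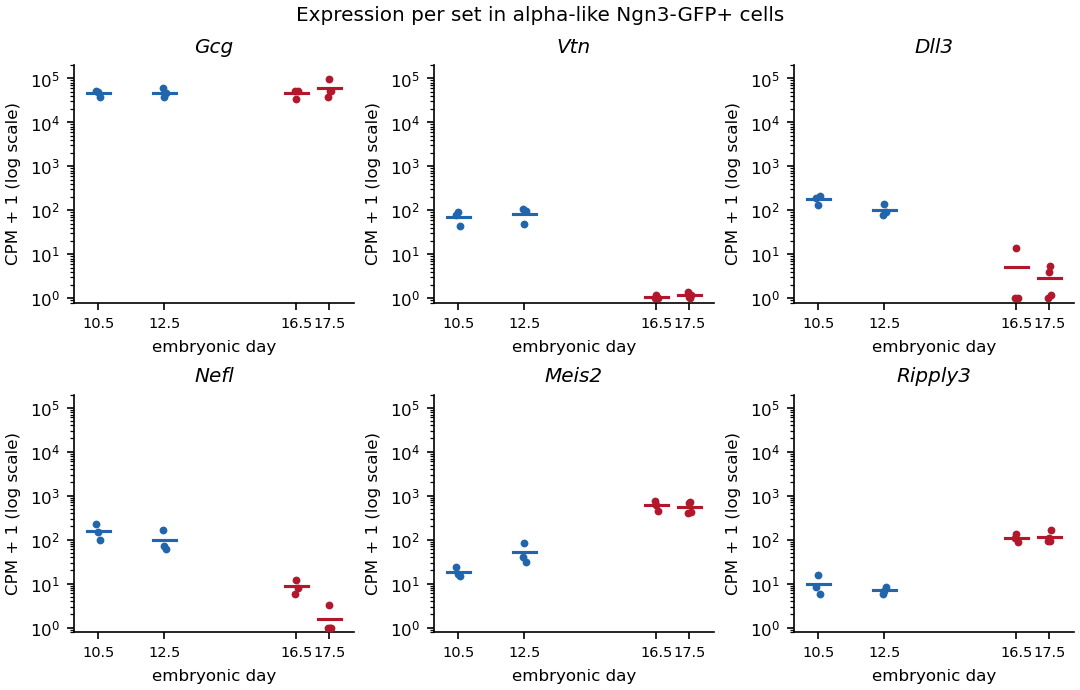
Mean CPM plus 1 on a log axis of 6 genes in the alpha-like cells of Ngn3-GFP+ at E10.5, E12.5, E16.5 and E17.5; points are sets and bars the mean of the sets. Vtn averaged 77.0 CPM in the early and 0.129 CPM in the late sets, and Gcg 47430 and 53970 CPM.

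Ins1-RFP+ and Gcg-GFP+ cells of E15.5 contrasted the beta and alpha cell lineages by their hormone reporters (n = 2 sets each). The cells were sorted on reporters of Ins1 and Gcg, so the differences in these genes follow from the sort. Ins1 stood at 36130 ± 12540 against 80.4 ± 30.7 CPM (log2 fold change 8.81 ± 0.57, adjusted p = 0.00190, edgeR) and Ins2 at 65910 ± 3178 against 45.7 ± 42.6 CPM. Higher in Ins1-RFP+ cells were Sytl4 (13.85), the GLP-1 receptor gene Glp1r (11.30), the glucose transporter gene Slc2a2 (9.02) and Pdx1 (4.58), and Pax4 was at least 421-fold higher. Higher in Gcg-GFP+ cells were the thyroid hormone carrier gene Ttr (793 ± 94.97 against 8790 ± 2234 CPM, log2 fold change -3.47 ± 0.29), the alpha cell transcription factor Irx2 (-7.58), Etv1 (-6.95), the signalling regulator Rgs4 (-10.06) and the glutamate receptor gene Gria2 (-7.80). The fibrinogen gene Fgb was at least 871-fold lower in Ins1-RFP+ cells. Gcg itself averaged 16.2 ± 4.67 against 53140 ± 6320 CPM and did not pass (log2 fold change -11.67 ± 2.08, adjusted p = 0.0551, edgeR). Of 17 tested beta cell genes, 13 passed as higher (15 adjusted over the list alone), at adjusted p = 1.52e-20 by camera and 0.0112 with an estimated correlation. Of 12 tested alpha cell genes, 5 passed as lower (9 adjusted over the list alone), at adjusted p = 2.33e-07 by camera and 0.368 with an estimated correlation. Of 7 tested liver genes, 3 passed as lower (7 adjusted over the list alone), at adjusted p = 7.34e-10 by camera and 0.0775 with an estimated correlation. At least 4 liver markers were carried by 1 of 36 Gcg-GFP+ cells (2.78%) and 0 of 39 Ins1-RFP+ cells. Of 4 tested mesenchyme genes, 1 passed as lower (2 adjusted over the list alone), at adjusted p = 0.0215 by camera and 0.368 with an estimated correlation. In all, 174 of 16617 genes passed, 95 higher and 79 lower in Ins1-RFP+ cells. An unadjusted p under 0.05 was found for 2464, and DESeq2 called 1580. The split was 180 higher and 269 lower in limma on log2 mean CPM per cell. The count was 14 or 56 without Ins1-RFP+ set 1 or 2 and 58 or 35 without Gcg-GFP+ set 1 or 2. Ins1, Sytl4 and Rgs4 passed in all 4 of these fits, Pax4, Glp1r, Irx2, Gria2 and Fgb in none. Etv1 lost its call in 3, Pdx1 in 2, and Ins2, Slc2a2 and Ttr in 1.

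Sox9-CreER cells, marked through a gene of duct and progenitor cells, were set against Ngn3-GFP+ cells of E16.5 and E17.5 (n = 4 and 8 sets). The metalloprotease gene Adamts9 (ENSMUSG00000030022, mm10 chromosome 6, 92772699 to 92943492) was higher in Sox9-CreER cells, with 773 ± 88.3 against 22.1 ± 27.2 CPM (log2 fold change 5.22 ± 0.87, adjusted p = 0.000494, edgeR), as were the keratin gene Krt23 (5.93), the acinar granule gene Sycn (4.68), Hes1 (3.92) and Sox9 (2.21). Hormone and granule genes were lower. Gcg stood at 12.02 ± 13.8 against 17490 ± 8241 CPM (log2 fold change -10.58 ± 1.09). Ins2 had a log2 fold change of -13.20, the secretogranin gene Scg2 -11.76 and the chromogranin gene Chga -4.46, and G6pc2 was at least 6210-fold lower. Spp1 did not pass (log2 fold change 3.05 ± 1.15, adjusted p = 0.0651, edgeR). Of 17 tested pan-endocrine genes, 17 passed as lower (17 adjusted over the list alone), at adjusted p = 2.82e-18 by camera and 0.0598 with an estimated correlation. Of 12 tested alpha cell genes, 12 passed as lower (12 adjusted over the list alone), at adjusted p = 1.76e-16 by camera and 0.0230 with an estimated correlation. Of 17 tested beta cell genes, 15 passed as lower (17 adjusted over the list alone), at adjusted p = 6.79e-17 by camera and 0.0319 with an estimated correlation. Of 5 tested delta, epsilon and PP cell genes, 4 passed as lower (4 adjusted over the list alone), at adjusted p = 0.00403 by camera and 0.0930 with an estimated correlation. Of 16 tested S phase genes, 15 passed as higher (15 adjusted over the list alone), at adjusted p = 1.35e-08 by camera and 0.225 with an estimated correlation. Of 15 tested duct genes, 8 passed as higher (13 adjusted over the list alone), at adjusted p = 0.000107 by camera and 0.280 with an estimated correlation. Of 8 tested leukocyte genes, 2 passed as lower (2 adjusted over the list alone), at adjusted p = 0.0302 by camera and 0.6247 with an estimated correlation. The Notch pathway list had 5 of 12 higher and 2 lower, with adjusted p = 0.0360 by camera and 0.388 with an estimated correlation. In all, 4764 of 19059 genes passed, 2164 higher and 2600 lower, against 2063 at E16.5 alone and 2639 at E17.5 alone. Of the Sox9-CreER cells, 41 of 55 at E16.5 fell in a cluster with acinar markers and 29 of 34 at E17.5 in one with duct markers, so the pooled values mix the types. The median log2 fold change of all tested genes was -0.17. Krt23 did not pass on either day alone, nor did Sox9, Hes1 and Chga at E16.5 or Sycn at E17.5. Without Sox9-CreER E16.5 set 1 the count was 3130, and Sox9 lost its call in 9 of 12 fits without 1 set, and Hes1 and Krt23 in 1.

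Pdx1-Cre cells, which descend from cells that expressed Pdx1-Cre, were followed as a slope per day from E10.5 to E15.5 (n = 19 sets). Digestive enzyme genes of acinar cells rose. Ctrb1 (ENSMUSG00000031957, mm10 chromosome 8, 111686519 to 111691010), which encodes chymotrypsinogen, had a slope of 2.88 ± 0.17 log2 units per day (adjusted p = 1.55e-09, edgeR). It went from 3.33 ± 2.19 CPM over the E10.5 and E11.5 sets (n = 4) to 14900 ± 20250 CPM over the E14.5 and E15.5 sets (n = 7). The elastase gene Cela3b (3.83 ± 0.36), the lipase genes Pnliprp1 (2.09 ± 0.16) and Cel (1.85 ± 0.20) and the acinar transcription factors Bhlha15 (1.26) and Rbpjl (1.24) rose as well. Nepn (ENSMUSG00000038624, mm10 chromosome 10, 52388972 to 52404625), a marker of early gut endoderm, fell by 1.98 log2 units per day ± 0.36, from 2571 ± 1376 to 3.48 ± 7.13 CPM. The ERK-dependent transcription factor Etv4 (-1.15), the growth factor binding protein gene Igfbp2 (-0.90), the Wnt antagonist gene Sfrp5 (-1.10) and Onecut2 (-1.02) fell too. Of 13 tested acinar genes, 12 passed as rising (12 adjusted over the list alone), at adjusted p = 1.11e-25 by camera and 0.00684 with an estimated correlation. Of 12 tested unfolded protein response genes, 5 passed as rising (8 adjusted over the list alone), at adjusted p = 8.67e-06 by camera and 0.280 with an estimated correlation. Of 11 tested immediate early genes, 5 passed as rising (6 adjusted over the list alone), at adjusted p = 1.62e-06 by camera and 0.0504 with an estimated correlation. Among these, Fos had a slope of 1.16 and Egr1 one of 0.96 per day. Of 12 tested multipotent progenitor genes, 1 passed as falling (5 adjusted over the list alone), at adjusted p = 0.00296 by camera and 0.0725 with an estimated correlation. Of 8 tested liver genes, 0 passed as falling (0 adjusted over the list alone), at adjusted p = 0.0173 by camera and 0.462 with an estimated correlation. The ERK feedback and target list had 2 of 19 rising and 4 falling, with adjusted p = 0.0296 by camera and 0.462 with an estimated correlation. The hormone genes Ins2 (1.503) and Sst (2.29) and the collagen gene Col3a1 (2.47) rose with an SD above their mean, Sst to 269 ± 709.8 and Col3a1 to 256 ± 675 CPM. Cells with mesenchyme markers numbered 4 of 79 at E15.5 and 1 of 108 at E13.5. Those with neural and glial markers were 0 of 80 at E10.5 and at E11.5 (up to 3.75%), 6 of 131 at E12.5 (4.58%), 14 of 108 at E13.5 (12.96%), 8.73% at E14.5 and 4 of 79 at E15.5. Without cells of other types 943 genes passed, 600 rising and 343 falling, and Col3a1 lost its call. In all, 747 of 16343 genes passed, 509 rising and 238 falling. In limma on log2 mean CPM per cell 389 rose and 594 fell, and the hormone genes and Col3a1 did not pass. Of the named genes, Ins2 and Col3a1 lost their call without E15.5 set 1, Sst and Fos without E15.5 set 2 (where the slope of Sst was 0.31, and without set 1 that of Col3a1 1.20), Onecut2 without E10.5 set 2, and Egr1 in 6 of 19 fits without 1 set.

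**Figure D4:**
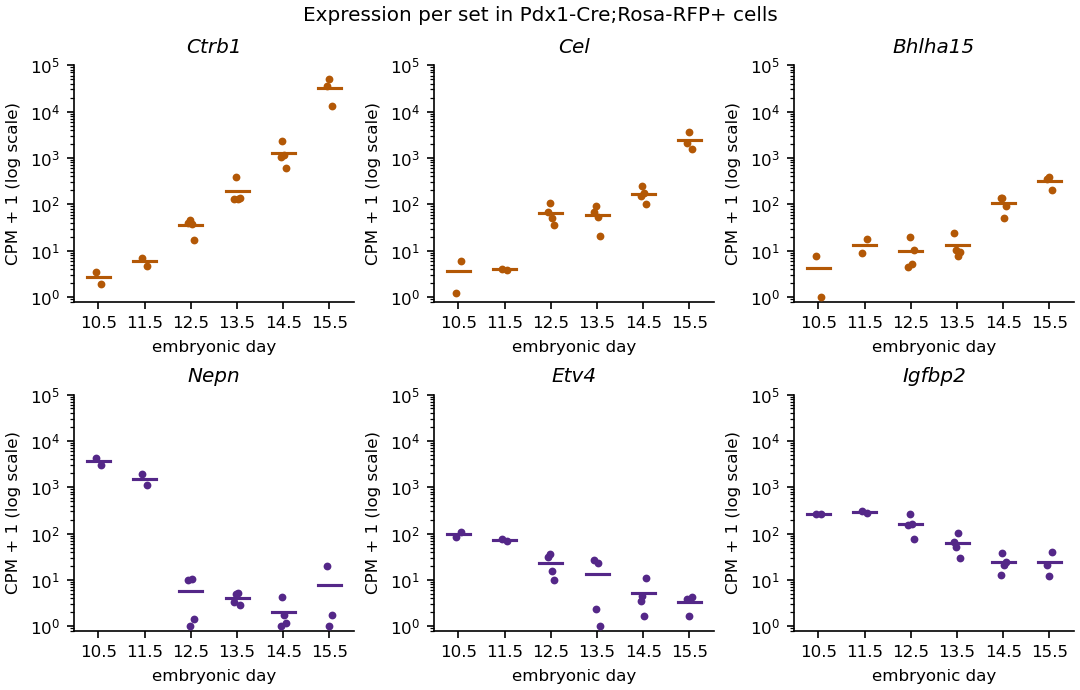
Mean CPM plus 1 on a log axis of 6 genes in Pdx1-Cre cells, E10.5 through E15.5; points are sets and bars the mean of the sets. Ctrb1 averaged 3.33 CPM over the E10.5 and E11.5 sets and 14900 CPM over the E14.5 and E15.5 sets, and Nepn 2571 and 3.48 CPM.

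The share of Pdx1-Cre cells over 100 CPM was related to day for 8 genes (Benjamini-Hochberg over the 8), and none passed. The progenitor and acinar factor Ptf1a had the largest correlation, with 16.4% ± 0.421 of cells at E10.5 (n = 2) and 56.6% ± 6.95 at E15.5 (n = 3). The rise was not even over the days. Over the 7 sets of E14.5 and E15.5 the share was 33.85% ± 22.26, from 9.09% to 62.5%. Over the 4 sets of E10.5 and E11.5 it was 14.69% ± 3.56. Ptf1a had Pearson's r 0.557 (permutation p = 0.0115, adjusted 0.0921), Spearman's rho 0.338 (permutation p = 0.156) and r 0.661 without the 2 farthest sets, but r -0.0133 at 10 CPM. At 1000 CPM, the carboxypeptidase gene Cpa1 passed (r 0.664, permutation, adjusted p = 0.0103), against r -0.0405 at 100 CPM.

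Pdx1-GFP+ cells, sorted on the reporter of an early pancreas and duodenum factor, were compared between E11.5 and E9.5 (n = 2 and 3 sets). Nepn was lower at E11.5, with 852 ± 74.5 against 3483 ± 818 CPM (log2 fold change -2.03 ± 0.20, adjusted p = 0.0132, edgeR), as was Dpysl5, with 73.5 ± 0.53 against 329 ± 78.2 CPM (-2.16 ± 0.26). Genes of macrophages were higher, namely the protease gene Ctss (10.37), the complement genes C1qb (9.88) and C1qc (9.54) and Cx3cr1 (8.25). So were the apolipoprotein gene Apoe (3.70 ± 0.33) and Stab1 (5.85), which was named after its values were seen. Of 8 tested leukocyte genes, 2 passed as higher (8 adjusted over the list alone), at adjusted p = 6.72e-18 by camera and 0.00559 with an estimated correlation. Of 8 tested liver genes, 0 passed as higher (2 adjusted over the list alone), at adjusted p = 0.00119 by camera and 0.384 with an estimated correlation. Of the cells, 2 of 60 E11.5 cells (3.33%) and 0 of 113 E9.5 cells (up to 2.65%) carried at least 4 leukocyte markers. In all, 8 of 16670 genes passed, 6 higher and 2 lower, against 1626 at an unadjusted p under 0.05 and 576 by DESeq2. Without the cells with leukocyte or other markers edgeR called 0 genes, as it did without E11.5 set 1 or 2 or E9.5 set 3, and 15 without E9.5 set 1. Of the 5 fits without 1 set, Ctss and Stab1 lost their calls in all, Nepn and Dpysl5 in 4, and C1qb, C1qc, Cx3cr1 and Apoe in 3.

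At E10.5, Pdx1-GFPhigh cells were set against Pdx1-GFP+ cells (n = 2 sets each). The sorts also differed in median counts per cell (1085200 and 1231430 against 710687 and 641405) and in the share of the 10 most abundant genes (11.7% and 8.77% against 19.1% and 19.1%). They share no set number, so effects of the sort and of the libraries cannot be told apart. The progenitor transcription factor Sox11 (ENSMUSG00000063632, mm10 chromosome 12, 27334264 to 27342574) was higher in Pdx1-GFPhigh cells, with 354 ± 162 against 50.6 ± 15.99 CPM (log2 fold change 2.81 ± 0.47, adjusted p = 0.0482, edgeR), and Sox9 stood at 626 ± 1.15 against 208 ± 19.8 CPM (1.59 ± 0.24). The chromatin gene Hmga2 (2.75), the growth factor feedback gene Spry2 (2.40) and Marcks (2.01) were higher, and Nfatc2 (-3.56), the Notch-modifying gene Mfng (-2.84) and the G protein gene Gnas (-2.29) lower. Of 18 tested G2/M genes, 0 passed as higher (8 adjusted over the list alone), at adjusted p = 1.52e-05 by camera and 0.566 with an estimated correlation. Of 4 tested erythroid genes, 0 passed as higher (0 adjusted over the list alone), at adjusted p = 0.000296 by camera and 0.566 with an estimated correlation. In all, 87 of 16670 genes passed, 34 higher and 53 lower. In limma on log2 mean CPM per cell the split was 337 and 237. The count was 0 without Pdx1-GFP+ set 3 or 4, 1 without Pdx1-GFPhigh set 1 and 1030 without Pdx1-GFPhigh set 2, and each gene named here lost its call in 3 of these 4 fits.

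Cells traced by Ptf1a-CreER (n = 3 sets) and by Ngn3-Cre (n = 2) were each compared with Pdx1-Cre cells of E11.5 (n = 2), a contrast of lineages on one day. No gene passed by edgeR in either, and the list calls below rest on the preset correlation. On simulated data of the Ptf1a-CreER comparison, 0%, 27.5% and 30% of genes changed by 1, 2 and 3 log2 units were called. Of 9 tested erythroid genes, 0 passed as higher (8 adjusted over the list alone), at adjusted p = 7.12e-06 by camera and 0.626 with an estimated correlation. Erythroid markers were carried by 2 of 79 Ptf1a-CreER cells (2.53%). Also called were, as lower, the alpha cell (camera, adjusted p = 1.99e-05), pan-endocrine secretory (2.74e-05), beta cell (0.000288) and late endocrine precursor lists (0.0494). As higher, these were the S phase (camera, adjusted p = 9.76e-06), cholesterol synthesis (0.000857) and G2/M lists (0.00108). With an estimated correlation none of these lists passed, at adjusted p = 0.626 or more. Every Ptf1a-CreER set and no Pdx1-Cre E11.5 set carries a tissue tag in its titles. The labels do not say what the tag marks, so lineage and what the tag stands for cannot be told apart here. In Ngn3-Cre cells, of which 2 of 44 carried erythroid markers and 2 neural and glial ones, the erythroid list was called as higher, with adjusted p = 0.0272 by camera and 0.576 with an estimated correlation. The G2/M list had a median log2 fold change of -1.22 there, with adjusted p = 2.14e-09 by camera and 0.558 with an estimated correlation. Also called were, as lower, the S phase (camera, adjusted p = 0.000341), ERK feedback and target (0.000933), multipotent progenitor (0.00674) and Notch pathway lists (0.0330). As higher, these were the leukocyte (camera, adjusted p = 0.00180), pan-endocrine secretory (0.00674), alpha cell (0.0188), late endocrine precursor (0.0311) and beta cell lists (0.0312). With an estimated correlation none of these lists passed, at adjusted p = 0.497 or more, and 0 of the 44 cells carried leukocyte markers (up to 6.82%). Cells with at least 4 mesenchyme markers made up 6 of 44 Ngn3-Cre cells (13.6%). For Ptf1a-CreER edgeR called 0 of 16679 genes (1099 at an unadjusted p under 0.05), limma 0 and DESeq2 208 (78 higher and 130 lower). Without Ptf1a-CreER set 1 edgeR called 36. For Ngn3-Cre edgeR called 0 (939 at an unadjusted p under 0.05), limma 0 and DESeq2 188 (88 higher and 100 lower), and edgeR called 1 without Ngn3-Cre set 2.

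U0126, which inhibits the kinases MEK1 and MEK2 upstream of ERK, was tested on Ins1-RFP+ cells of cultured dorsal pancreata (n = 4 sets each). The insulin gene Ins1 averaged 25240 ± 4651 against 22260 ± 3992 CPM with the inhibitor and in controls, and Ins2 37310 ± 4770 against 35530 ± 4493 CPM. The ERK feedback and target list was also set down beforehand as a single test. Without a block its unadjusted camera p was 0.00641, with a median log2 fold change of -0.75 over 14 tested members. It did not pass when adjusted over the lists (camera, adjusted p = 0.0546), with an estimated correlation (p = 0.186) or by fry (p = 0.192). With the set number as a replicate block its camera p was 5.19e-05 (adjusted 0.000519, against 0.368 with an estimated correlation and 0.128 by fry), and without control set 4 and no block it was 0.0501. The block also gave list calls for immediate early (camera, adjusted p = 4.14e-07, lower), alpha cell (0.0379, lower), beta cell (0.0356, higher) and delta, epsilon and PP cell genes (0.0356, lower). None of these 4 passed with an estimated correlation under the block (adjusted p = 0.368, and 0.586 for alpha cell). Etv5, a transcription factor downstream of ERK, stood at 10.8 ± 9.81 against 23.01 ± 5.44 CPM (log2 fold change -1.09 ± 0.90) and the immediate early gene Egr1 (ENSMUSG00000038418, mm10 chromosome 18, 34859823 to 34864984) at 90.3 ± 149.6 against 227 ± 313 CPM (-1.33 ± 1.15). Without 1 set the value of Egr1 ran from -3.85 to 0.31, turning without control set 4. Of the 14 members 4 had a positive log2 fold change, Ccnd1 (1.42 ± 1.34), Myc (1.29 ± 1.20), Dusp6 (0.16 ± 1.32) and Phlda1 (0.01 ± 0.35), and no member passed. With the replicate block Dusp6 turned to -1.19 and Phlda1 to -0.01. The immediate early list had a median of -0.67, with adjusted p = 0.0546 by camera and 0.692 with an estimated correlation. Of 12 tested unfolded protein response genes, 0 passed as higher (3 adjusted over the list alone), at adjusted p = 0.0331 by camera and 0.495 with an estimated correlation. All cells in either arm held Ins1, Ins2 and Chga over 100 CPM. None held that much of Gcg or the proliferation gene Mki67, which allows shares of up to 5.17% of the controls. Neurog3 was over 100 CPM in 3.75% ± 4.79 and 5.42% ± 7.86 of cells (exact permutation p = 0.886, with 0.0286 the smallest p that 4 sets against 4 allow). By edgeR 0 of 12632 genes passed (436 at an unadjusted p under 0.05), by limma 0 and by DESeq2 27 (14 higher and 13 lower). On simulated data of this design, 11.9%, 50.8% and 64.7% of genes changed by 1, 2 and 3 log2 units were called.

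The droplet libraries surveyed unsorted E14.5 pancreas beside the sorted E14.5 Pdx1-Cre cells, and their values have no replicate test. Mesenchyme-like cells were the most frequent class, 47.7% of 3402 cells in library 1 (exact 95% interval 46.02 to 49.4) and 38.4% of 6575 in library 2 (37.2 to 39.6). Acinar-like cells made up 11.1% (10.0 to 12.2) and 14.6% (13.74 to 15.46), and duct-like cells 9.94% (8.95 to 11.0) and 6.40% (5.82 to 7.02). Alpha-like cells made up 4.76% (4.07 to 5.53) and 3.97% (3.51 to 4.47), and endocrine progenitors 2.82% (2.29 to 3.44) and 3.33% (2.91 to 3.79). Beta-like (2.72%) and late precursor clusters (3.35%) were named in library 2 only, and 15.4% and 18.8% of cells had no name. Under other settings 62 class shares left their interval and 120 did not. Neurog3 had a UMI (a count of one tagged molecule) in 26.95% of epithelial and 0.49% of mesenchyme-like cells of library 1 and in 27.3% and 1.47% in library 2. Their median depths were 16482 and 7912 UMIs in library 1 and 9232 and 3835 UMIs in library 2. Ins2 had one in 9.98% and 1.97% in library 1 and in 42.6% and 15.9% in library 2, and Gcg in 24.1% and 9.30% and in 37.1% and 12.4%. The shares in mesenchyme-like cells mark the background. Mean profiles of epithelial cells correlated across 14241 genes with r 0.964 between the libraries and 0.778 and 0.806 with Smart-seq2, genes not being independent replicates. Epithelial cells had a median of 3509 and 2827 detected genes by droplets and 6911 by Smart-seq2.

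**Figure D5:**
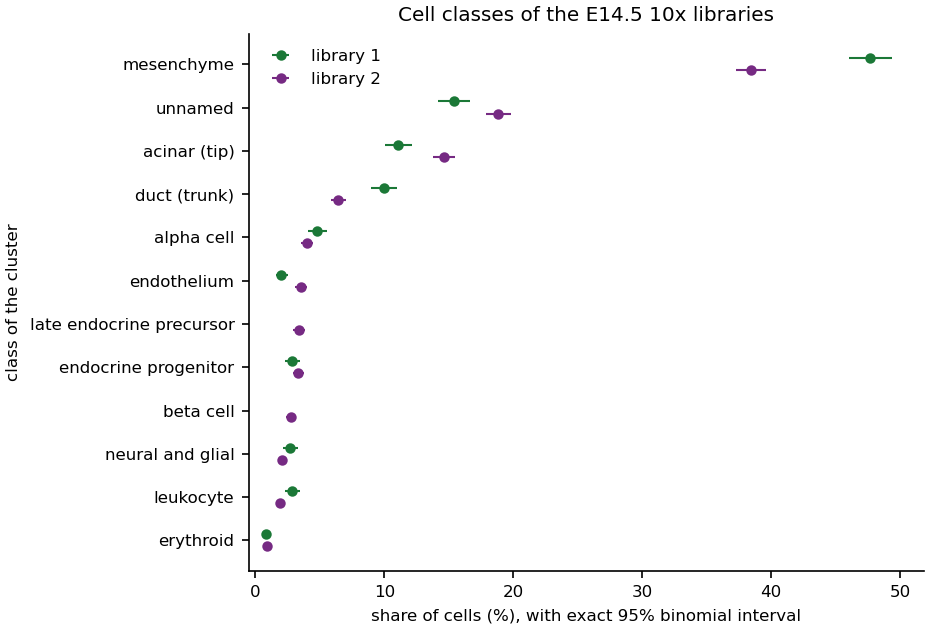
Percent of cells per named class in droplet libraries 1 and 2 of E14.5 pancreas; points are shares and bars their exact 95% binomial intervals, and a class without a named cluster in a library has no point. Mesenchyme-like cells made up 47.7% and 38.4%.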

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

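The tests without cells that carry leukocyte markers, on all lower genes, and without the sets with a tissue tag were chosen after the results were seen, the others in this part before. Of 175 values per set or share in groups of 4 to 10 sets, 26 (14.86%) lay far from the other sets of their group by Dixon's test, which picks about 5% by chance.

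In the Ngn3-GFPlow sort, the genes that were lower in Ngn3-GFPhigh cells at E13.5 may in part stem from leukocytes among the sorted cells, a type that a sort on Ngn3-GFP does not name, whose marker Csf1r averaged 1485 CPM. Without the cells with leukocyte markers the median log2 fold change of 805 such genes went from -3.74 to -1.78, against -3.84 without as many random cells. The fit then called 97 genes lower, against 876 with all cells and 648 without as many random cells. A difference in total counts between the sets is argued against, since 930 lower genes were called with every set thinned to 11344092 counts. The thinning did not even out depth per cell. For the called S phase and G2/M genes the median was -3.91 with and -3.33 without those cells, over the 80% of it that was set beforehand to speak against leukocytes. That bound was set aside after the value was seen, since 1 of 16 calls was left against 8 without random cells and the upper quartile was -1.28, so leukocytes stay open for these genes, as does a biological difference between the sorts.

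At E13.5, 1181 genes passed, against at most 0 in the other 9 of 10 splits of the sets, which are too few for a share under 0.05. Of those, 3 part all 3 same-numbered pairs as the real one does and 6 part 1. At E14.5, 2857 passed against at most 396 in 56 splits (1 as large), so that chance is unlikely there. A share of 1 in 56 is the smallest that these splits allow.

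Between early and late alpha-like cells 893 genes differed, against at most 1 in the other splits (100 splits, 1 as large), so that chance is unlikely. A difference in total counts between the sets is argued against, since 824 of these genes were called again with every set thinned to 5684314 counts. The thinning did not even out depth per cell, whose median was 1109850 counts in early and 803876 in late cells. Depth per cell therefore stays open. Cells with insulin counts are argued against as the whole source, since 735 were called again without alpha-like cells of at least 1000 CPM of Ins2. Leaving out cells with markers of other types removed 0 of 168 cells and called 893, a test that could decide nothing. A biological difference between the waves, which may underlie the pattern, was not tested apart from the days of sorting.

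The trend of 747 genes over the days in Pdx1-Cre cells was larger than in any of the other splits (at most 32 genes in 100 splits, 1 as large), so that chance is unlikely. In the 17 sets without a tissue tag 687 genes passed, and 634 of the 747 were called again, so these calls do not rest on the tagged sets. Only E12.5 set 4 and E14.5 set 4 carried the tag, and neither day ends the range. Leaving them out could hardly have ended most calls, so the test decides nothing further on what the tag stands for. Without the 6 genes that take over 1% and together up to 21.5% of a set's counts, 736 of 743 other calls were made again. A few abundant genes are thus argued against as the whole source. A difference in total counts between the sets is argued against too, since 644 of the trend genes were called again with every set thinned to 2838610 counts. Depth per cell was not evened out by this. Development over the days may explain the pattern and was not tested apart from them. For the remaining comparisons with enough sets, 3757 genes passed between early and late Ngn3-GFP+ cells against at most 515 in 100 splits. Between Sox9-CreER and Ngn3-GFP+ cells 4764 passed against at most 171 in 100 splits, each real split being the 1 as large, so that chance is unlikely. For U0126 the real split called 0 genes, so that all 35 of 35 splits call as many whatever the data, and the count says nothing about chance. Of the other 7 splits that part all 4 same-numbered pairs, none called a gene. The highest other split called 35 genes and set numbers 1 and 2 of both arms against 3 and 4, so that the set numbers have a structure of their own, which the block takes up.

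The difference between the Ngn3-GFP sorts differed between E13.5 and E15.5 for 23 genes by the interaction test. Single sets lay far from the rest of their group in the following values. Among alpha-like Ngn3-GFP+ cells of E17.5, set 2 had 15060 CPM of Ins2, 2.32 CPM of Nefl and 2.23 CPM of Prtg. In Ngn3-GFPlow cells of E14.5, set 3 had 7.39 CPM of Fev, and set 5 had 0.758 CPM of G6pc2, 51.1 CPM of Neurod1 and 20290 CPM of Spp1. In Pdx1-Cre cells of E13.5, set 1 had 23.7 CPM of Bhlha15, set 2 had 382 CPM of Ctrb1, and set 3 had 70.1 CPM of Col3a1, 6.24 CPM of Sfrp5 and 17.9 CPM of Sst. In Pdx1-Cre cells of E14.5, set 2 had 7.0 CPM of Egr1 and set 4 had 3.90 CPM of Sst, and at E12.5 set 1 had 115 CPM of Fos. U0126 set 4 had 315 CPM of Egr1. In Ngn3-GFP+ cells of E16.5, set 3 had 20.6 CPM of Apoa1 and set 2 had 28470 CPM of Gcg. In Ngn3-GFP+ cells of E17.5, set 3 had 24.2 CPM of Cx3cr1, set 2 had 55240 CPM of Ins1 and 51.98 CPM of Sycn, and set 1 had 3.90 CPM of Krt23. The share of cells over 100 CPM of Gcg was 13.51% in Ngn3-GFP+ E16.5 set 1, 56.2% in Pdx1-Cre E13.5 set 2 and 50% in Pdx1-Cre E14.5 set 1, and that of Mki67 was 25% in Pdx1-Cre E13.5 set 3. Outside every comparison, the Gcg-GFP+ cells of E17.5 had a median of 78840 CPM of Gcg, and ERCC spike-ins made up a median of 2.54% of a cell's counts.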

How the results depend on the processing

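Chosen after the results were seen were the fits without cells of other types, without sets with a tissue tag, without parts of the alpha-like cells and at single days of the Sox9-CreER comparison. So were a marker score of 0.3, joint clustering, and for the ERK list under U0126 no filter and only sets of at least 10 cells, all others before. Of the values of named genes under the alternatives, 1890 kept their direction and side of the threshold, 290 kept the direction and lost the call, 6 gained one and 18 reversed. Of the list tests 1560 kept and 304 lost the call. The counts and values that answer a comparison stayed within 1.5 times or past their threshold in 209 cases, moved in 86 and crossed 0.05 in 3. Of the droplet class shares 120 stayed within their interval and 62 left it. The causes of the changes below were not tested, except that fits without a set or with fewer cells rest on fewer data. Counts of genes called by the DESeq2 Wald test were 27 (U0126, against 0), 2700, 4534 and 3842 (Ngn3-GFP sorts at E13.5, E14.5 and E15.5, against 1181, 2857 and 1706) and 731 (their change, against 23). It also called 1580 (Ins1-RFP+, against 174), 1622 (Pdx1-Cre trend, against 747), 576 (Pdx1-GFP+, against 8), 2033 (Pdx1-GFPhigh, against 87), 208 and 188 (Ptf1a-CreER and Ngn3-Cre, against 0) and 2133 (alpha-like cells, against 893). Limma on log2 mean CPM per cell called 1837 (E13.5: 730 higher and 1107 lower), 2746 (E15.5), 115 (change), 449 (Ins1-RFP+), 149 (Pdx1-GFP+), 574 (Pdx1-GFPhigh) and 1579 (alpha-like). Without a filter on low counts, 510 (Ins1-RFP+), 1826 (trend), 92 (Pdx1-GFP+), 362 (Pdx1-GFPhigh), 3 (Ptf1a-CreER) and 1 (Ngn3-Cre) were called. Without cells of other types, the counts were 156, 1774 and 785 (Ngn3-GFP sorts by day), 39 (change), 0 (Pdx1-GFP+, where edgeR had 8) and 2268 (Ngn3-GFP+ early and late, against 3757). With the set number as a replicate block, 732, 1173 (E14.5), 2 (change), 53 (Ins1-RFP+), 0 (Pdx1-GFP+), 2017 (Sox9-CreER, against 4764) and 527 (alpha-like) were called. In the paired comparisons it changed 0 list calls at E13.5, where Lhx1 and Hes1 lost theirs, and under U0126 added 5 list calls, with the ERK list at adjusted p = 0.000519 by camera. At E14.5 the correlations of same-numbered sets were 0.214, 0.0746 and 0.102, each set correlating best with its own number. No paired analysis was possible because Pdx1-GFPhigh and Pdx1-GFP+ sets of E10.5 share no set number. The Sox9-CreER count was 2063 at E16.5 and 2639 at E17.5 alone, and the alpha-like count 420 with sets of at least 10 cells. Of 122 list calls, 10 were made with an estimated correlation and 77 by fry, where the ERK list under U0126 had p = 0.186 and 0.192. Leaving out 1 set gave ranges of 0 to 0 (U0126), p = 7.82e-05 to 0.0501 (its ERK list), 408 to 1284 (E13.5), 1571 to 2973 (E14.5), 354 to 742 (E15.5) and 7 to 238 (change). Further ranges were 14 to 58 (Ins1-RFP+), 507 to 856 (trend), 0 to 15 (Pdx1-GFP+), 0 to 1030 (Pdx1-GFPhigh), 2704 to 3772 (Ngn3-GFP+) and 3130 to 4981 (Sox9-CreER). They were 0 to 36 (Ptf1a-CreER), 0 to 1 (Ngn3-Cre), 575 to 860 (alpha-like) and, for shares, 0 to 0 (Pdx1-Cre), 3 to 7 (Ngn3-GFP+) and 0 to 0 (U0126). A lone set left in an arm is assumed to vary like the other groups. Shares called were 1 at 1000 CPM over the days of Pdx1-Cre and 3 at 10 CPM in Ngn3-GFP+. The correlation of library 1 with Smart-seq2 was 0.748 with joint clustering, where 654 and not 972 cells were epithelial, as were 521 at the higher resolution and 592 with at least 2000 genes per cell. None of the reversed log2 fold changes belongs to a called gene. They were those of Ins2 under U0126 (-0.0134 without control set 2, the range without 1 set reaching 0.127) and Egr1 (0.31 without control set 4, from -3.85). Dusp6 under U0126 turned to -0.696 in limma, -1.57 without sets with a tissue tag, -1.19 with the replicate block, -0.235 without control set 1 and -1.84 without U0126 set 4, the range reaching 0.57. Phlda1 there turned to -0.0272 in limma, -0.0315 without sets with a tissue tag, -0.00895 with the replicate block, and -0.0411, -0.0690, -0.00927 and -0.168 without control set 3, control set 4, U0126 set 1 and U0126 set 2, the range reaching 0.16. Others were Ins2 at E13.5 (-0.23 without cells of other types, -0.66 without Ngn3-GFPhigh set 2 and -0.06 without Ngn3-GFPlow set 1, up to 2.30) and Gcg in alpha-like cells (0.0233 without E17.5 set 2, from -0.273). Correlations with day of the Pdx1-Cre share turned for Ptf1a (-0.0133), Neurog3 (-0.163) and Ins1 (0.171) at 10 CPM. They also did for Cpa1 (0.664, which passed) and Ins1 (0.309) at 1000 CPM, Ins1 with sets of at least 10 cells (0.0523), and Cpa1 without E11.5 set 2 (0.0171, from -0.178) and E14.5 sets 1 (0.0152) and 4 (0.0169). Differences in share turned for Pyy (10.4 points at 1000 CPM and 0.479 without E10.5 set 1, from -9.33) and, under U0126, Neurog3 (2.08 without control set 3, from -3.75). Under U0126 the differences of Gcg (-9.69 at 10 CPM), Chga (-6.88) and Ins2 (0.200) at 1000 CPM were 0 at 100 CPM.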

Other observations

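The way of naming droplet clusters was chosen after its output was seen, and no test was made of the values in this part. The Gcg-GFP+ cells of E17.5 (11 cells of 1 set) all held Gcg, with a median of 78840 CPM and a range of 9675 to 139900 CPM. The thyroid hormone carrier gene Ttr had a median of 5731 CPM and the amino acid transporter gene Slc38a5 of alpha cells 4171 CPM, and each was over 100 CPM in all 11 cells. The alpha cell gene Irx2 (51.6 CPM) was over 100 CPM in 4 cells. Other hormone genes were found at lower medians: Ins2 at 673 CPM, Ppy at 359 CPM, Ins1 at 308 CPM and Sst at 3.47 CPM. The proliferation gene Mki67 was over 100 CPM in 0 of the 11 cells, which allows a share of up to 27.3%.

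In the droplet libraries, cells of other tissues were named beside the pancreatic ones. Endothelium-like cells made up 2.00% and 3.53% of libraries 1 and 2, leukocyte-like cells 2.82% and 1.89%, neural and glial-like cells 2.67% and 2.05%, and red blood cell-like cells 0.852% and 0.928%. The acinar gene Cpa1 had a UMI in 48.3% of epithelial and 11.8% of mesenchyme-like cells of library 1 and in 57.6% and 15.2% in library 2. Spp1 had one in 67% and 3.70% and in 55.6% and 5.98%. Fev had one in 15% of epithelial and 0 of 1623 mesenchyme-like cells of library 1, which sets no limit on the cells that express it, and in 7.92% and 0.119% of library 2. The median log2 difference between Smart-seq2 and droplet profiles was 0.39, 1.27, 1.36 and 1.08 over 4 bins of rising gene length.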
